A study of Homo sapiens with 17 samples.

How the data were processed

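The study measured where on RNA 6 proteins were bound in 293T cells, a human embryonic kidney line. The assay was eCLIP, in which ultraviolet light fixes proteins to the RNA they touch, an antibody pulls down 1 protein, and the RNA fragments that come with it are sequenced. Per the labels' protocols, plated cells received 400 mJ per square cm at 254 nm, lysates were treated with RNase I, and complexes were cut from a membrane in a window that reached 75 kDa above the protein. The proteins were AIFM1, NUMA1, RANGAP1, RNF219, VIM and ZNF184. Each protein had 1 size-matched input, which is RNA from the same gel window without immunoprecipitation. The 17 samples were 11 eCLIP libraries and 6 inputs. Groups and replicate numbers came from the sample titles. AIFM1, NUMA1, RANGAP1, VIM and ZNF184 had 2 replicates each and RNF219 had 1 library. The series calls the replicates biological, and no more is said about how they were grown. The protocol allows barcoded replicates, or proteins of similar size, to be pooled after the first ligation, and which libraries were pooled is not given in the sources used here.

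The submitters' processing notes name cutadapt, STAR, GATK, Picard and SAMtools and the genome build hg19, with no versions. The peak caller and any removal of PCR duplicates are not given in the sources used here. The deposited files were 11 peak lists, 1 for each eCLIP library and none for pooled replicates. Each list gave position, strand and a pair of values per peak. The first was the authors' -log10 p of the peak against the size-matched input, and the second was the authors' log2 fold over that input, deposited without adjustment for the number of peaks as far as the lists show. These values belong to the authors throughout. In all 11 lists, peaks below input carried a -log10 p of 0, and -log10 p did not go above 400. No input library had a list of its own, so inputs entered only through the folds.

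The folds of a library were ratios of whole numbers times 1 constant. The constant equals the depth of the input over the depth of the eCLIP library and was found from the commonest folds and their p-values. With it, between 94.7% and 98.8% of the folds in a library were ratios of at most 200 eCLIP reads to at most 50 input reads, to within 1e-07 on the log2 scale. With a wrong constant 0% were. Between 98.3% and 99.9% of the p-values above 0 and short of saturation then matched an exact or chi-square p to within 0.005 on the log10 scale. The reads given here are these recovered numbers. Where p was saturated, or 0 as for peaks below input, only the least whole numbers with that ratio are known. Reads printed for such peaks are given as "at least". On a simulated library of 5000 peaks, both read numbers were right for 100% of the 2439 peaks that settled. The simulated p-values came from the same exact formula that the recovery inverts. The simulation therefore checks the arithmetic and not the deposited lists. An input of 0 reads could not be told from 1 read. Total reads per library are unknown.

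A peak counted as significant with -log10 p of at least 3 and log2 fold of at least 3, which is 8-fold. These thresholds, the tests and the alternatives were fixed before the data were examined, except where stated. Shares of peaks have 95% Wilson intervals, which take peaks as independent. They can be too narrow where several peaks are pieces of 1 site. Peaks were merged into regions where they shared at least 1 nt on the same strand. A region was reproducible when both replicates had a significant peak in it. Fisher's exact test (2-sided) asked whether significance in replicate 1 went with significance in replicate 2, among peaks of replicate 1 that overlapped a peak of replicate 2. Both replicates of a protein were set against the same input, so 100 draws without binding were simulated with a shared input, for the overlapping peaks of replicate 1 with settled reads, and set against the observed values of these peaks. Lists were compared by the Jaccard index, the shared over all merged regions. An exact permutation test (2-sided) compared replicate pairs with all other pairs over the 945 ways to pair 10 libraries. On simulated lists with 65 planted shared regions in a pair, 65 were found. Shares on the mitochondrial chromosome were compared between the libraries of a protein and the others by an exact permutation test (2-sided) over the 55 choices of 2 from 11 libraries, or 11 choices for RNF219, with Benjamini-Hochberg adjustment over 6 proteins. With 55 choices the smallest p is 0.0182, and with 11 choices 0.0909, so that no outcome can fall below 0.05 after the adjustment. Where a share was 0, the limit given is 3 counts of the total.

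The number of eCLIP reads needed beside 1 input read differed between libraries. Folds on the mitochondrial chromosome and in clusters were therefore also compared under a common minimum of input reads. The matched difference is the median log2 fold of peaks there with at least 10 input reads minus the median of the other peaks of the same list, off the mitochondrial chromosome, with at least 10 input reads. For peaks below input or with saturated p, the least whole numbers stood in for the input reads. Such a peak could be left out although its true input reached the minimum. Between 28.2% and 91.4% of the mitochondrial peaks of a library were below input. Clusters were runs of at least 10 merged significant sites of any library on 1 strand with gaps of up to 5000 nt, and were tested where every library had at least 3 peaks with that many input reads. The matched difference and the clusters were chosen after the data were seen. Only the minimum was common to both sets of peaks. Input reads above it were not matched, so the level of input can still differ between the sets. In ZNF184 replicate 2, 174 of 177 mitochondrial peaks passed the minimum, and 13639 other peaks of a list of 53807.

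No genome sequence or annotation in hg19 was used here, and the gene table at hand has another build. Positions are therefore given without gene, exon or UTR. The planned region shares, gene list tests, gene overlaps, sequence motifs and the proteins' own mRNAs were not analysed here. The regions named follow the rule set for that case: the 5 regions per protein with the highest lower-of-replicates log2 fold, ties by the lower -log10 p, and for RNF219 the 5 peaks with the highest log2 fold. Starts and ends are 1-based. Alternatives were other thresholds for p and fold, a wider overlap, lists of 500 peaks, the overlap coefficient, a replicate block and leaving out each replicate. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.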

Results

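The 11 eCLIP peak lists held between 10682 peaks, in VIM replicate 1, and 63198 peaks, in ZNF184 replicate 1. The proteins were candidate RNA-binding proteins, and the question was where on RNA each was enriched over its size-matched input. AIFM1 is a flavoprotein of mitochondria, NUMA1 a protein of the nucleus and spindle poles, RANGAP1 the activator of the Ran GTPase, VIM the intermediate filament protein vimentin and ZNF184 a zinc finger protein. The depth of the input over that of the eCLIP library ranged from 0.534 in AIFM1 replicate 2 to 4.84 in VIM replicate 1. Beside 1 input read, a peak needed at least 23 eCLIP reads to be significant in the former library and 5 in the latter. Counts of significant peaks therefore describe each library against its own input. Reads recovered from the folds can hold PCR copies, and the intervals cover counting error only.

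ZNF184 had the longest lists of significant peaks and AIFM1 the shortest. In ZNF184, 1989 peaks of replicate 1 (3.15% of its deposited peaks, 95% Wilson interval 3.01 to 3.29) and 2592 of replicate 2 (4.82%, 4.64 to 5.00) were significant. RANGAP1 had 810 (1.52%, 1.42 to 1.63) and 1542 (2.99%, 2.85 to 3.14). NUMA1 had 675 (1.51%, 1.40 to 1.63) and 261 (0.877%, 0.777 to 0.989). VIM had 565 (5.29%, 4.88 to 5.73) and 650 (4.50%, 4.17 to 4.85) out of 10682 and 14443 deposited peaks. RNF219 had 228 in its 1 library (0.926%, 0.814 to 1.05). AIFM1 had 26 (0.216%, 0.147 to 0.316) and 68 (0.214%, 0.169 to 0.272). The median significant peak held 25.5 and 45 eCLIP reads in AIFM1, 31 in RNF219, 15 and 15 in RANGAP1, 14 and 10 in NUMA1, 18 and 17 in ZNF184 and 7 and 8 in VIM, over the peaks with settled reads. The median input count of these peaks was 2 or 3 reads. Each count depended on the thresholds, and a log2 fold of at least 4 left 13 and 26 peaks in AIFM1 and 670 and 1139 in ZNF184.

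**Figure D1:**
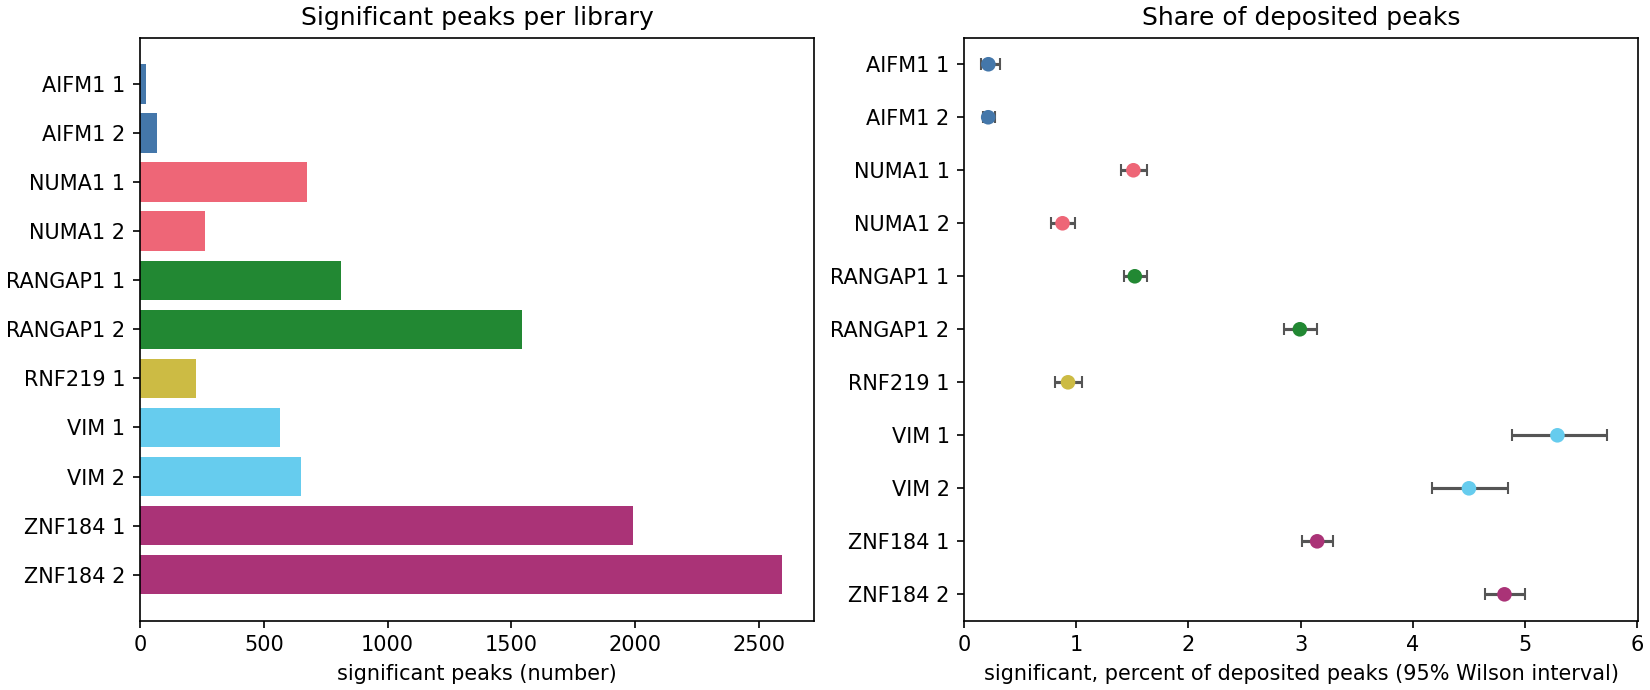
Significant peaks in each of the 11 eCLIP libraries as a number (bars, left) and as percent of the deposited peaks (points, right, with 95% Wilson intervals); colours mark the protein. ZNF184 has the most peaks, 1989 and 2592, and VIM replicate 1 the highest share, 5.29%.

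Between replicates, ZNF184 had 550 reproducible regions, RANGAP1 341, VIM 171, NUMA1 64 and AIFM1 13. Among peaks of replicate 1 that overlapped a peak of replicate 2, those significant in replicate 1 were also significant in replicate 2 in 73.1% (19 of 26) for AIFM1, 65.7% (619 of 942) for ZNF184, 64.4% (368 of 571) for RANGAP1, 56.0% (202 of 361) for VIM and 30.1% (71 of 236) for NUMA1. Among the peaks that were not significant in replicate 1 the share was 0.552%, 3.66%, 3.52%, 5.83% and 0.874% in the same order. Fisher's exact p (2-sided, across peaks, which are not replicates) was 2.03e-35 for AIFM1, 3.57e-77 for NUMA1 and 4.69e-116 for VIM, and too small to compute for RANGAP1 and ZNF184, where the odds ratios were 49.7 and 50.4. Independent lists would share 0.240 peaks for AIFM1, 3.51 for NUMA1, 29.7 for RANGAP1, 41.3 for VIM and 59.8 for ZNF184.

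Spearman's rho of log2 fold between replicates, across peaks, was 0.751 in AIFM1, 0.803 in ZNF184, 0.855 in NUMA1, 0.861 in RANGAP1 and 0.900 in VIM. Draws without binding that shared the input were made for the peaks with settled reads, 3767 in AIFM1, 17155 in ZNF184, 7910 in NUMA1, 17305 in RANGAP1 and 2481 in VIM. Over these peaks the observed rho was 0.622, 0.762, 0.759, 0.805 and 0.841 in the same order, and the draws gave 0.525, 0.381, 0.289, 0.361 and 0.250. The covariance of the log2 folds over these peaks was 0.925 in ZNF184, 0.614 in NUMA1, 0.698 in RANGAP1 and 1.43 in VIM, against 0.206, 0.212, 0.257 and 0.238 in the draws. In AIFM1 it was 0.436, below the 0.492 of the draws. Reads settled only for replicate 1 peaks above input with p short of saturation, while the drawn folds had no such limit. Observed and drawn rho and covariance therefore do not cover the same range of folds. Over all overlapping AIFM1 peaks the covariance was 1.15. At most 1 of the peaks with settled reads was significant in both replicates in a draw. Observed were 13 in AIFM1, 483 in ZNF184, 55 in NUMA1, 328 in RANGAP1 and 120 in VIM. The shared input could not be split. With the input of another protein under replicate 2, at peaks present in both proteins, the mean rho with replicate 1 was 0.0874 for AIFM1, 0.0287 for NUMA1, 0.167 for RANGAP1, 0.484 for VIM and 0.0648 for ZNF184. The other protein's own eCLIP reads over that input had a mean rho with replicate 1 of 0.229, 0.193, 0.138, 0.374 and 0.186 in the same order, so that only RANGAP1 and VIM were above this reference.

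The strongest RANGAP1 region lay on chromosome 17 (18965402 to 18965452, plus strand), with log2 folds of 8.93 and 8.85 from at least 330 and 259 eCLIP reads. It was also the first region of VIM (18965398 to 18965451; 8.30 and 8.01) and of AIFM1 (18965398 to 18965452; 6.30 and 5.69), and the fourth of NUMA1 (18965394 to 18965452; 6.43 and 7.84). A site on chromosome 6 (31958260 to 31958279, plus strand) was second for RANGAP1, at 6.82 and 6.98. The same site, split into 3 abutting pieces with equal values, took the first 3 places of NUMA1 at 6.79 and 7.08. For AIFM1 it held place 3 (31958259 to 31958279; 5.77 and 4.98). AIFM1 and VIM had another 2 leading regions in common. The region on chromosome 4 (minus strand) had log2 folds of 5.19 and 4.65 in AIFM1 (13544061 to 13544098) and 7.98 and 8.20 in VIM (13544062 to 13544098). The region on chromosome 2 (plus strand) had 6.19 and 4.56 in AIFM1 (219824447 to 219824480) and 7.48 and 8.34 in VIM (219824450 to 219824479). The remaining AIFM1 region was on chromosome 2 (230045637 to 230045715, minus strand), at 5.04 and 5.78.

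Other leading regions belonged to 1 protein's list of 5, which does not mean that other proteins lacked them. The ZNF184 pieces on chromosome 6 below lay in a site that was significant with 5 proteins, in 10 libraries. In ZNF184 they were a pair on chromosome 22, minus strand (42335675 to 42335703, at 7.72 and 7.65, and 42335741 to 42335784, at 7.64 and 8.40), 1 on chromosome 19, plus strand (48112258 to 48112282, at 9.13 and 7.31), and abutting pieces on chromosome 6, plus strand (10887839 to 10887859, at 7.07 and 8.19, and 10887836 to 10887838, at 7.06 and 8.18). In RANGAP1 they were abutting pieces on chromosome 11, minus strand (32165337 to 32165350 and 32165351 to 32165358, both at 6.32 and 6.78), and 1 region on chromosome 13, minus strand (74014625 to 74014646, at 5.52 and 6.04). VIM had regions on chromosome 21, plus strand (9825923 to 9825965, at 7.42 and 7.68), and chromosome 1, plus strand (148241532 to 148241573, at 7.74 and 7.18). NUMA1 had 1 on chromosome 1, plus strand (75210278 to 75210301, at 5.37 and 5.57). For most of these folds p was saturated, so that their input reads are known only as a minimum. The NUMA1 region on chromosome 1 had 23 and 15 eCLIP reads beside 1 input read each, and the 95% Clopper-Pearson intervals of its log2 folds ran from 2.75 to 10.7 and from 2.87 to 10.97.

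By Jaccard index, replicates of a protein shared more of their significant regions than libraries of different proteins did. By count this did not hold for AIFM1, whose replicates shared 13 regions. AIFM1 replicate 1 shared 14 with ZNF184 replicate 2. AIFM1 replicate 2 shared 23 with ZNF184 replicate 2, 17 with each VIM library and 15 with NUMA1 replicate 2. The other AIFM1 pairs shared 12 or fewer. The mean Jaccard index was 0.152 ± 0.0473 (SD, n = 5 pairs) within proteins and 0.0174 between them (40 pairs, range 0.00387 to 0.0724). The difference of the means was 0.135, with an exact permutation p of 0.00106, the smallest that 945 pairings can give. The lowest pair within a protein, NUMA1 at 0.0742 with 64 shared regions, was only just above the highest between proteins. That was NUMA1 replicate 2 with VIM replicate 1, at 0.0724 with 54 shared regions. With VIM replicate 2 it was 0.0683 with 57, so NUMA1 replicate 2 was about as near to VIM as to its own replicate. Replicates of a protein shared an input and different proteins did not, so the comparison does not separate the protein from its input. RNF219, with 1 library, had Jaccard indices of 0.000566 to 0.0292 with the other 10 libraries.

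**Figure D2:**
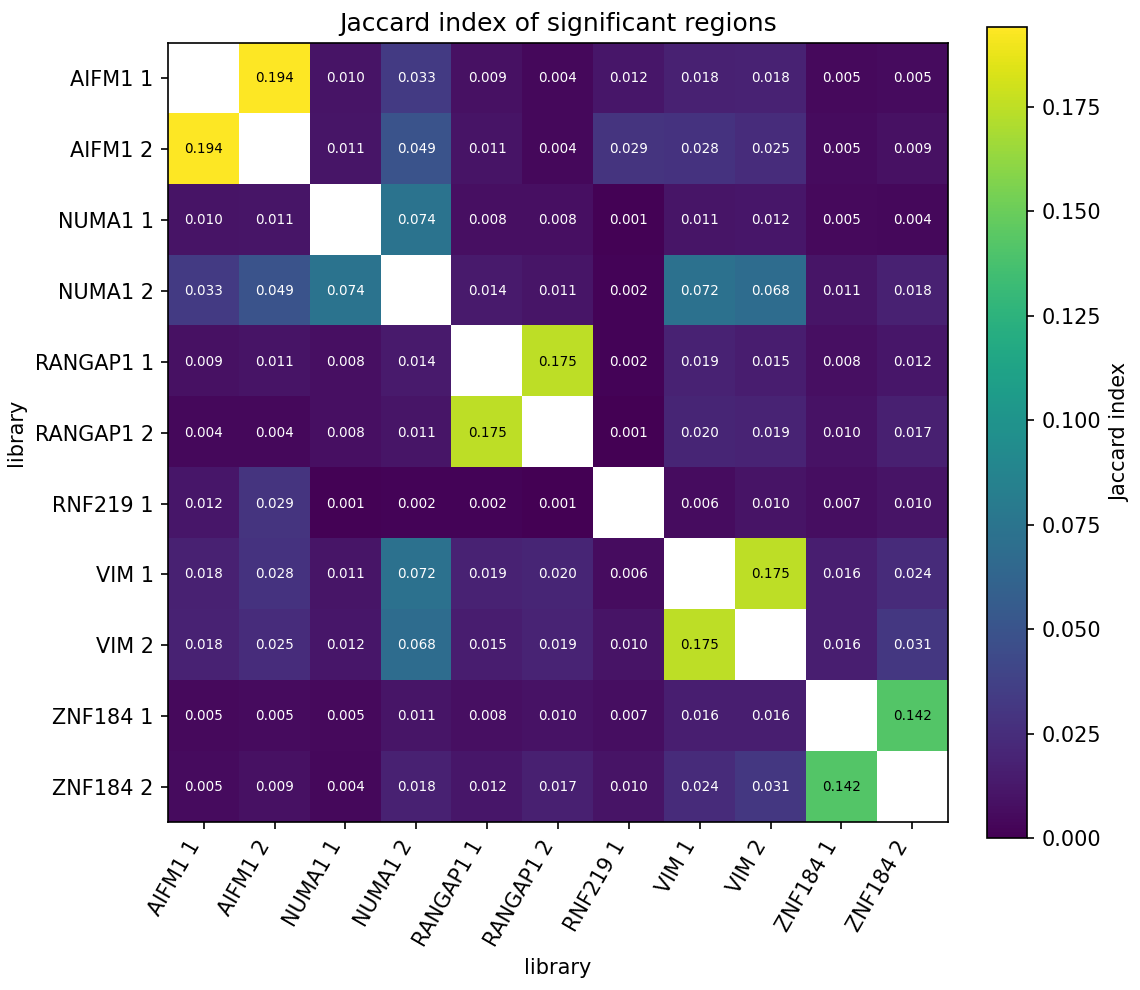
Jaccard index of significant regions for each pair of the 11 libraries, with the value printed in each cell and brighter colours for higher values. The 5 replicate pairs reach 0.0742 to 0.194, and pairs of different proteins with replicates stay at or below 0.0724.

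ZNF184 and RANGAP1 had mostly regions of their own. In ZNF184, 467 of 550 reproducible regions (84.9%, 95% Wilson interval 81.7 to 87.7) were significant in no library of another protein. The number was 281 of 341 (82.4%, 78.0 to 86.1) in RANGAP1, 171 of 228 significant peaks (75.0%, 69.0 to 80.2) in RNF219, 44 of 64 (68.8%, 56.6 to 78.8) in NUMA1 and 79 of 171 (46.2%, 38.9 to 53.7) in VIM. In AIFM1 it was 1 of 13 (7.69%, 1.37 to 33.3). The other 12 AIFM1 regions were shared with at least 1 other protein, and all 12 still were when the ZNF184 libraries were left out. A region of 1 protein could miss significance elsewhere for want of reads: 28.4% to 44.9% of the ZNF184 regions had a deposited peak in each other library, and 17.0% to 59.2% of those of RANGAP1.

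Merging all lists gave 7422 significant sites, of which 7073 were significant with 1 protein, 288 with 2, 46 with 3, 8 with 4, 6 with 5 and 1 with all 6. The site of all 6 proteins was that on chromosome 6 (31958259 to 31958286, plus strand), significant in 11 libraries with log2 folds of 3.66, in RNF219, to 7.48, in VIM replicate 1. The RNF219 value came from 18 eCLIP reads beside 1 input read, the least that passes in that library. Sites of 5 proteins were on chromosome 17 (18965394 to 18965452, plus strand; 5.69 to 8.93 in 10 libraries), chromosome 6 (10887833 to 10887860, plus strand), chromosome 2 (230045564 to 230045722, minus strand), chromosome 11 (77597616 to 77597689, plus strand), chromosome 1 (237766448 to 237766589, plus strand) and the mitochondrial chromosome (5828 to 5859, minus strand). RNF219 had no deposited peak at 4 of these 7 sites.

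RNF219 and AIFM1 replicate 2 had the highest shares of significant peaks on the mitochondrial chromosome. In RNF219 it was 53 of 228 (23.2%, 95% Wilson interval 18.2 to 29.1), and these 53 peaks lay at 29 merged sites. In AIFM1 it was 16 of 68 in replicate 2 (23.5%, 15.03 to 34.9) and 2 of 26 in replicate 1 (7.69%, 2.14 to 24.1). The AIFM1 replicate 2 peaks lay at 10 merged sites. These libraries also had the lowest depth ratios of input over eCLIP, 0.701 in RNF219 and 0.534 and 1.22 in AIFM1 replicates 2 and 1. Every other library had at least 1.36, so the shares cannot separate the protein from depth. VIM, with ratios of 4.84 and 3.27, had the next highest shares. The share was 0.885% and 1.54% in VIM, 0.151% and 0.270% in ZNF184 and 0.247% in RANGAP1 replicate 1. It was 0 of 1542 in RANGAP1 replicate 2, which allows a share of up to 0.195% (3 counts of the total), and 0 of 675 and 0 of 261 in NUMA1, which by the same limit allow up to 0.444% and 1.15%. The AIFM1 mean was 15.6% ± 11.2 (SD, n = 2) against 2.93% ± 7.64 (SD, n = 9) in the other libraries, with an exact permutation p of 0.0364 and an adjusted p of 0.218. With this many libraries no outcome could have passed after adjustment. Without AIFM1 replicate 2 the difference went from 12.7 to 4.77 percentage points. For RNF219 the exact permutation p was 0.182 (n = 1 against 10), where 11 choices allow no p below 0.0909.

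Among peaks with at least 10 input reads, the median log2 fold of mitochondrial peaks minus that of other peaks was 1.67 in RNF219. In AIFM1 it was 0.46 and 0.42. It was -1.12 and -1.69 in RANGAP1, -0.28 and -0.52 in NUMA1, -1.22 and -0.64 in VIM and -0.94 and -1.07 in ZNF184. The AIFM1 mean of 0.44 ± 0.03 (SD, n = 2) against -0.65 ± 0.96 (SD, n = 9) had an exact permutation p of 0.164. RNF219 had an exact permutation p of 0.0909 (n = 1 against 10), the smallest 11 choices allow. Of 6 proteins tested, the lowest adjusted p was 0.327. The side of 0 on which AIFM1 lay depended on the minimum of input reads: replicate 2 was at -0.22 with at least 20 input reads, and replicate 1 at -0.24 with no minimum. RNF219 was at 1.33 and 0.97 under these settings, above every other library. The 5 strongest RNF219 peaks were all mitochondrial: 15959 to 15989 on the minus strand at 9.03, and on the plus strand 10009 to 10050 at 8.45, 597 to 634 at 7.62, 1542 to 1567 at 7.41 and 1009 to 1013 at 7.05.

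**Figure D3:**
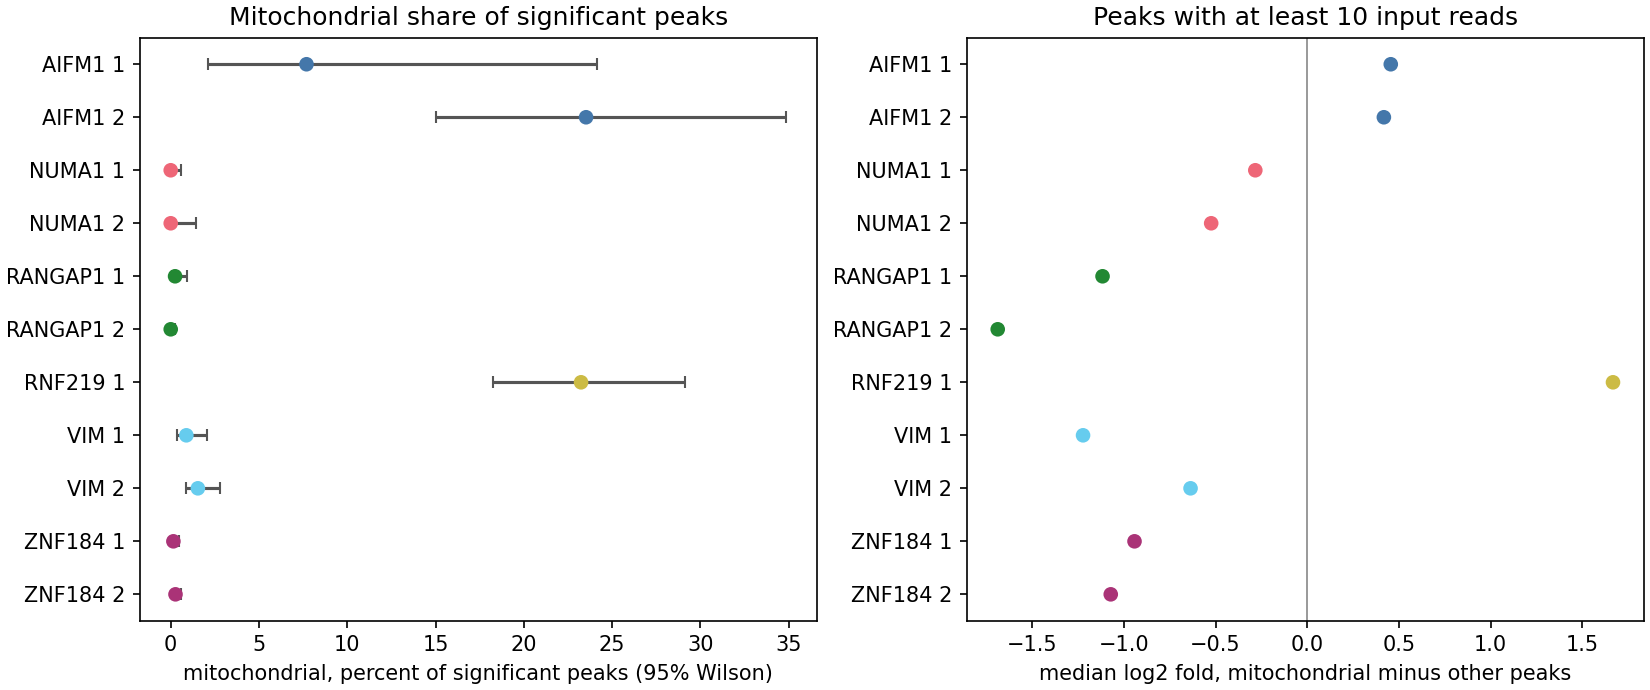
Percent of significant peaks on the mitochondrial chromosome (left, points with 95% Wilson intervals) and median log2 fold of mitochondrial minus other peaks with at least 10 input reads (right), for the 11 libraries. RNF219 at 1.67 and both AIFM1 libraries at 0.46 and 0.42 are above 0 on the right, and the other 8 libraries are below 0. The libraries above 0 are also those with the lowest depth of input over eCLIP. With at least 20 input reads AIFM1 replicate 2 is at -0.22, and with no minimum AIFM1 replicate 1 is at -0.24.

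Significant sites also lay in runs. There were 32 clusters of at least 10 sites off the mitochondrial chromosome. A pair of clusters on the minus strand of chromosome X had the most sites, 38 (73041127 to 73047796) and 36 (73063840 to 73072514). In the first, RNF219 had 16 significant peaks and ZNF184 17 and 36, with none in the other 8 libraries. In the second, RNF219 had 16, VIM 3 and 10, and ZNF184 0 and 16. Altogether 54 of 228 significant RNF219 peaks (23.7%, 95% Wilson interval 18.6 to 29.6) were on chromosome X, against 0% to 6.44% in the other libraries. RNF219 alone had significant peaks in a cluster on chromosome 22 (38880913 to 38886774, minus strand; 12 peaks), and it had 12 in 1 on chromosome X (107963265 to 107967872, minus strand), where each ZNF184 library had 1. ZNF184 alone had significant peaks in a cluster on chromosome 22 (42335309 to 42336318, minus strand), 12 and 16. RANGAP1 alone had them in a cluster on chromosome 19 (41193113 to 41196602, minus strand), 4 and 9. In 7 clusters every library had enough input reads to be compared, and of 42 exact permutation tests 2 had an unadjusted p of 0.0182, the smallest that 55 choices allow (adjusted 0.294). No outcome could have passed adjustment over 42 tests, and the clusters were defined by significant peaks of the same libraries, so the tests only describe these values. The 2 were RANGAP1 in a cluster on chromosome 8 (37553310 to 37557480, plus strand), 2.06 ± 0.10 (SD, n = 2) against 0.26 ± 0.66 (SD, n = 9), and AIFM1 in the cluster on chromosome 22 where RNF219 alone had significant peaks, 1.11 ± 0.10 (SD, n = 2, from 4 and 5 AIFM1 peaks, none of them significant) against -0.19 ± 0.41 (SD, n = 9). Among peaks with at least 10 input reads, RNF219 was above every other library in both of the largest clusters. It was at 2.13 against at most 2.01 in the first and 1.84 against at most 0.76 in the second. With n = 1 against 10, 11 choices allow no p below 0.0909. With no minimum and against the library median, ZNF184 replicate 2 was above RNF219 in the first, at 1.13 against 0.97. In the second RNF219 stayed highest, at 0.38 against 0.26 in ZNF184 replicate 2.

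**Figure D4:**
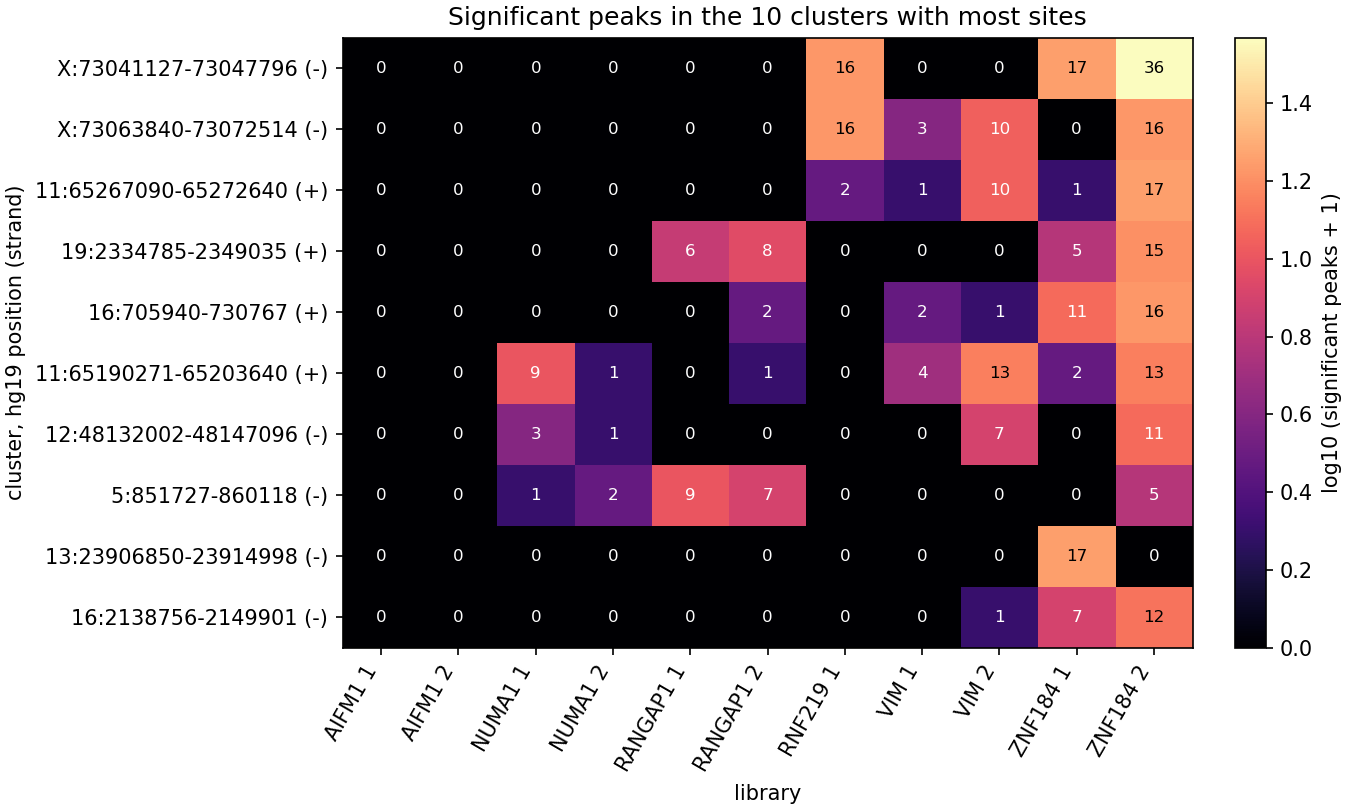
Number of significant peaks of each library (columns) in the 10 clusters with the most sites (rows, by hg19 position and strand); numbers are peaks and colours their log10 after adding 1. The top row holds 16 peaks of RNF219 and 17 and 36 of ZNF184 and none of the other libraries.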

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

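The tests of matched folds in this part, the comparison of read numbers at common sites, the count of control libraries and the draws with a shared input were chosen after the results were seen. The draws of random lists and the exchange of inputs were set out before their results were seen.

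At 7 places the replicates of 1 protein lay above the other peaks of their libraries with at least 10 input reads, and those of another below. At each place the protein with the highest mean was set against that with the lowest, so the differences are large by selection. The differences between these proteins were not tested themselves. On the mitochondrial chromosome, AIFM1 was 1.84 above RANGAP1 in mean matched log2 difference, though AIFM1 replicate 2 fell to -0.22 with at least 20 input reads and replicate 1 to -0.24 with no minimum. In the first X-chromosome cluster (73041127 to 73047796), ZNF184 was 2.71 above RANGAP1, and in the second (73063840 to 73072514), AIFM1 was 1.66 above RANGAP1. No AIFM1 peak in the second cluster was significant. On chromosome 11 (65267090 to 65272640, plus strand), VIM was 2.41 above RANGAP1, and 1.57 without VIM replicate 2. On chromosome 22 (38880913 to 38886774), AIFM1 was 1.65 above RANGAP1, from 4 and 5 AIFM1 peaks, none of them significant. On the plus strand of chromosome X (70753127 to 70767629), VIM was 2.12 above RANGAP1, and 1.14 without VIM replicate 2, from 4 and 7 VIM peaks. On chromosome 8 (37553310 to 37557480), RANGAP1 was 2.502 above NUMA1.

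The higher sharing within proteins (Jaccard 0.152 against 0.0174) was weighed against the input that replicates share. Poisson counting noise of that input is argued against within the limits of the draws. In 100 draws without binding at most 1 peak was significant in both replicates, against 13 to 483 observed among the peaks drawn. The draws took 1 rate per peak from its eCLIP and input reads together, and did not repeat the calling of peaks. Noise beyond Poisson was not drawn. For AIFM1 the covariance of folds over the peaks drawn was 0.436, against 0.492 in the draws. The observed peaks were limited to folds above input in replicate 1, and the drawn folds were not. This value therefore cannot show whether AIFM1 exceeds counting noise. Differences between input libraries beyond counting noise stay open and are a candidate explanation. With another protein's input under replicate 2, rho with replicate 1 was set against that of the other protein's eCLIP over the same input. The excess was -0.058 ± 0.12 (mean and SD over 5 proteins, above 0 in 2, VIM and RANGAP1). Simulated shared binding gave 0.43, binding with input differences of equal size 0.18 and input differences alone -0.12. The simulations had set effect sizes, equal depth of eCLIP and input, and no binding shared between proteins. They were not fitted to these libraries, whose depth ratios ran from 0.534 to 4.84, so they give no scale for -0.058. The exchange of inputs used 58 to 490 peaks each, at most 21 of them significant in both replicates, so it speaks mainly to other peaks. The biological explanation, binding by the protein, was not separated from the input.

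The 7 sites of 5 or 6 proteins exceeded the overlap of lists drawn at random from all deposited peaks. In 100 draws of lists of the same length there were at most 0 such sites. The draws were not matched on reads. Median eCLIP reads of a library were 4 to 9 over peaks with settled reads, and at least 46 over the significant values at these sites. Chance overlap among peaks with many reads therefore stays open. A chance low input count behind all folds at these 7 sites is argued against by the eCLIP reads. Their median was 4.6 times the least number that passes beside 1 input read (63 significant values). The median input count of these values was at least 2 reads, and eCLIP reads can hold PCR copies, so the argument is limited. Behind single proteins a chance low input count stays open. Of the values 3 were at that least number, among them RNF219 at the site of 6 proteins, and without these 3 values 6 of the 7 sites kept 5 proteins. With only values of at least 2 times that number 4 sites did and 3 did not. Background common to immunoprecipitations cannot be told apart from binding by several proteins, because 0 control immunoprecipitation libraries were used here.

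The position of mitochondrial peaks in RNF219 was weighed against depth. RNF219 stood at 1.67 in matched difference, above the highest other library, AIFM1 replicate 1 at 0.46. The depth ratio adds the same constant to every fold of a library and drops out of this difference. The rank of RNF219 therefore cannot test that constant as a cause. Depth can still bear on which peaks a list holds. The libraries with a matched difference above 0, RNF219 and both of AIFM1, also had the lowest depth ratios. All others had a ratio of at least 1.36, so depth and protein cannot be told apart here. AIFM1 replicate 2, with a depth ratio of 0.534 against 0.701, stood at 0.42, and 1 such library cannot decide this. RNF219 was also the highest library with at least 20 input reads (1.33) and with no minimum (0.97, against 0.58 in AIFM1 replicate 2). A property of 1 library preparation cannot be told apart from binding by RNF219, since 1 RNF219 library was used.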

How the results depend on the processing

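The tests with adjusted p, abutting pieces, common sites, input reads and matched folds were chosen after the data were seen. Sharing within against between proteins kept its direction and an exact permutation p of at most 0.00833 in every alternative run, with differences of 0.121 (without sites of 5 or more proteins) to 0.194 (overlap coefficient). The replicate block gave 0.135 with an exact permutation p of 0.00833, and leaving out each replicate gave 0.123 to 0.158. Pairs of different proteins with the same number had a mean Jaccard of 0.0180 and with other numbers 0.0168, so the numbers were not taken to pair samples. The block changed no call.

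Counts of significant peaks followed the thresholds by construction. With -log10 p of at least 5 they were 309 and 744 in RANGAP1, 247 and 112 in NUMA1, 229 and 248 in VIM and 991 and 1613 in ZNF184. With log2 fold of at least 4 they were 13 and 26 in AIFM1, 193 and 510 in RANGAP1, 210 and 86 in NUMA1, 89 in RNF219, 342 and 340 in VIM and 670 and 1139 in ZNF184. With at least 2 they were 56 and 162 in AIFM1, 2278 and 3587 in RANGAP1, 1865 and 645 in NUMA1, 439 in RNF219 and 4289 and 4348 in ZNF184. RNF219 without the mitochondrial chromosome and the pair of X-chromosome clusters had 143. Reproducible regions with -log10 p of at least 5 numbered 29 in NUMA1, 174 in RANGAP1, 102 in VIM and 334 in ZNF184. With log2 fold of at least 4 they numbered 8 in AIFM1, 14 in NUMA1, 64 in RANGAP1, 91 in VIM and 202 in ZNF184, and with at least 2, 35 in AIFM1, 243 in NUMA1, 1166 in RANGAP1 and 1128 in ZNF184. Without sites of 5 or more proteins AIFM1 had 7. Without either replicate only single lists remain: 26 to 68 regions in AIFM1, 261 to 675 in NUMA1, 810 to 1542 in RANGAP1, 565 to 650 in VIM and 1989 to 2592 in ZNF184.

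No mitochondrial share passed after adjustment under any alternative, and with this many libraries no outcome can, so this says nothing about stability. The AIFM1 difference ran from 4.77 percentage points without AIFM1 replicate 2 to 20.6 without replicate 1. The matched difference of NUMA1 from the other libraries, 0.06, was -0.18 with at least 5 input reads and -0.038 with no minimum; the cause was not tested. That of AIFM1, 1.08, was 0.35 with at least 20 input reads and 1.88 with no minimum, and AIFM1 replicate 2 (-0.22 with at least 20) and replicate 1 (-0.24 with no minimum) turned negative. That of VIM, -0.59, was -0.12 with at least 20, -0.16 with means, -1.19 with at least 5 and -1.72 with no minimum. That of ZNF184, -0.68, was -1.27 with means and -0.58 with no minimum. RANGAP1 ran from -1.35 to -0.82 about its -1.16, and RNF219 from 1.82 to 3.10 about its 2.33. The alternatives planned for region shares, gene lists, gene overlaps and motifs were not run, for want of an hg19 annotation and sequence.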

Other observations

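Mitochondrial sites differed between the libraries in which they were significant. Of 33 merged mitochondrial sites, 31 were on the plus strand, 29 were significant in RNF219, 10 in AIFM1 replicate 2 and 7 in both. Several were high in RNF219 alone: the site at 3185 to 3230 had a log2 fold of 6.98 in RNF219 and -0.04 in ZNF184 replicate 1, with no deposited peak in the other 9 libraries. The site at 1529 to 1567 had 7.41 in RNF219 and 0.77 in ZNF184 replicate 2. Others were higher in AIFM1 than in RNF219, such as 6226 to 6309, at 2.78 and 3.39 in AIFM1 and 1.06 in RNF219, and 3874 to 3921, at 2.28 and 3.10 against 0.92. The site at 1617 to 1656 was highest in ZNF184, at 5.13 and 4.53, and that at 4420 to 4461 was at 3.88 and 4.40 in VIM and 6.27 in RNF219. These sites were chosen after their values were seen.

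Some clusters were significant in 1 replicate and not the other. A cluster on chromosome 13 (23906850 to 23914998, minus strand) had 17 significant peaks in ZNF184 replicate 1 and 0 in replicate 2, as did 1 on chromosome 2 (238992162 to 238996861, plus strand; 12 and 0) and 1 on chromosome 11 (2671841 to 2681184, minus strand; 11 and 0). A cluster on chromosome 2 (178214044 to 178216013, minus strand) had 0 and 10. In a cluster on chromosome 12 (48132002 to 48147096, minus strand), VIM had 0 and 7 significant peaks and ZNF184 0 and 11. Replicate 1 of VIM and of ZNF184 had no deposited peak there. NUMA1 had significant peaks there in both replicates, 3 and 1. The cause was not tested.

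That a mitochondrial protein crosslinks to mitochondrial RNA more than the other proteins do was a hypothesis for AIFM1. The test of shares was set before the data were examined, and what the hypothesis predicts of it was written after the shares were seen. The adjusted exact permutation p was 0.218, in a design where no outcome passes after adjustment. The AIFM1 and RNF219 libraries also had the lowest depth of input over eCLIP, so the shares cannot separate the protein from depth. AIFM1 replicate 1, at 7.69%, was below RNF219, at 23.2%, and the hypothesis stays open.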
